A study of Oryza sativa Japonica Group with 19 samples.

How the data were processed

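Leaf RNA of 7 cultivars of japonica rice was measured on 19 one-colour (Cy3) Agilent rice arrays of 1 design, 4 arrays to a slide. Per the labels, each sample is RNA pooled from the blades of the third leaf, fully expanded, of 5 plants, so the samples of a cultivar are separate pools and the spread between them is the spread between pools. The hour of sampling is not given by the labels. The number of arrays limits the precision of each value.

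The deposited scanner files give, per the file headers, an intensity for each spot as processed by Agilent Feature Extraction 11.5.1.1, which subtracted a spatially detrended background, removed a multiplicative trend and put surrogate values in place of spots not above background. The authors' values were not normalized between arrays, and the deposited table of the whole series holds the same processed intensity for every spot (largest relative difference 0), on a linear scale and not centred, so it gave no separate alternative. Its medians over the spots used ran from 198.4 to 314.5 per array. Other columns hold, per the file headers, 0 or 1 marks per spot for being well above background, saturated or an outlier.

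Of 45151 spots, 43144 were used after control spots were left out. The log2 of the processed signal minus the array's 75th percentile was taken, outlier spots were left out, and spots of the same sequence were averaged, which gave 37896 probes. A probe was tested if it was well above background on every array of at least 1 cultivar, which left 27946 probes. Each locus was represented by its brightest probe among those naming that locus alone, which gave 20789 tested loci. Loci carry identifiers and descriptions as the array files give them. None of these identifiers matched the gene table of the reference, so no name was updated, and symbols of heading-date genes come from a list of loci fixed in advance. No genome sequence was used here, so positions are given as chromosome and locus order.

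A linear model with 1 mean per cultivar (12 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with moderated statistics from eBayes and Benjamini-Hochberg adjustment within each contrast at 0.05. All adjusted p-values of probes and loci are limma's, two-sided for a contrast and from the moderated F for the test over all cultivars. No cultivar is a control, so each was compared with the mean of the other 6 cultivar means. These 7 contrasts share arrays and are not independent of each other. A rise in 1 cultivar lowers the contrasts of the other 6 for the same probe. The 21 pairs of cultivars were also compared, with Hoshinoyume against Kitaake (both in group V) and Sorachi against Yukara (groups IIIa and IIIb) described in full. An error after ± is the standard error of the fitted difference unless it is called SD. Data were handled with the package data.table, version 1.17.8, with numpy 2.4.6 and Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

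A probe not well above background on any array of a group has only a bound there. Such differences are given as "at least N-fold", from the bright group's mean against, per array, the higher of the probe's own signal and the lowest signal of any probe well above background. Where this held for only some of the cultivars averaged on the dimmer side, those cultivars took that higher value and the difference is likewise "at least", a rule added after seeing the data.

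The 25 gene lists were built from words in the array's descriptions and, for heading date, from locus identifiers. The KNOX meristem list had 2 tested loci and was not tested. The other 24 were NB-ARC disease resistance genes, receptor-like kinases, pathogenesis-related proteins, diterpenoid phytoalexin enzymes, WRKY factors, heat shock proteins, photosystem proteins, Calvin cycle enzymes, ribosomal proteins, dividing-cell markers, flavonoid enzymes, jasmonate genes, cytochrome P450s, glutathione S-transferases, nitrogen, iron, phosphate, transposon, cold, senescence, root, seed storage, pollen and heading-date lists. Each was tested with camera (preset correlation 0.01) in 8 contrasts, 192 tests adjusted together, and with Fisher's exact test (two-sided) for its share of differing loci. Camera asks whether a list's loci are shifted against all other loci. It was repeated with a correlation estimated from the data, and fry, which asks only whether a list's own loci move one way on balance, was run beside it. Missing values were filled with the cultivar mean for camera and for the regroupings of arrays.

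Named loci followed a rule. They are the 20 described loci with the largest range of cultivar means, up to 5 highest and 5 lowest loci per cultivar for which every array of the cultivar lay outside the range of all other arrays, up to 10 per direction for each of the 2 described pairs, the 4 members with the largest difference of each list past its test, and the heading-date list, of which 1 locus is not reported here. Where several probes of a locus disagree, this is said beside it.

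Slide and scan were read from the file headers. The 19 arrays lie on 5 slides and were scanned in 6 runs on 1 day, so the day could not be a block. Slides 1 to 3 and slides 4 and 5 share no cultivar, so a fixed slide effect could be fitted for the test over all cultivars only in part (5 numerator and 9 residual degrees of freedom) and for both described pairs, and slide and scan entered the other comparisons as random blocks (correlations -0.079 and -0.04). Comparisons were also made within each slide that holds a pair of cultivars.

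Alternatives were normexp background correction (offset 50), quantile normalization, no filter on dim probes or one requiring all 19 arrays, outlier spots kept, an intensity trend in the prior, array weights, slide and scan blocks, the replicate number as a block, a difference of at least 1 on the log2 scale, adjustment over all contrasts, the mean of all probes of a locus, and each array left out in turn. The groups, tests, lists, rule for named loci and these alternatives were chosen before the data were examined. The comparisons within slides, the lists at a range of at least 3, and the loci set apart in 1 cultivar were chosen after seeing the data.

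Neighbouring loci were tested by permuting calls over the loci in their order along the chromosomes, one-sided, with 100000 permutations. The procedure was tested on simulated data with 200 changed probes per cultivar. In Akage (3 arrays) it found 63.6% of probes changed by 0.5, 80.6% of those changed by 1 and 95.5% of those changed by 2 on the log2 scale, and in Kitaake (2 arrays) 47%, 83.6% and 98.5%. A shifted simulated list was called and 0 of 24 unshifted ones were, and planted runs of neighbours gave p = 5e-04 while scattered calls gave p = 0.866 by permutation. The simulated probes varied independently of each other, so false calls of lists whose members vary together were not tested. Only 200 of 27946 simulated probes were changed, while 18486 were called in Akage. The adjustment depends on that share, so the rates found need not hold for the reported fits.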

Results

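Transcript levels were measured in the third leaf blade of 7 rice cultivars that the series places in groups numbered I to V: Akage (group I, 3 arrays), Hayayuki (II, 3), Sorachi (IIIa, 3), Yukara (IIIb, 2), Norin No.15 (IV, 3), Hoshinoyume (V, 3) and Kitaake (V, 2). The plants were grown together in a greenhouse and no cultivar served as a control. What the grouping rests on is not stated in the labels. On each array, between 63.6% and 74.3% of the 43144 spots used were well above background and 0 were saturated. The lowest share belonged to Hayayuki 2, which also held 801 outlier spots, and the highest to Hayayuki 1. Akage 1 had the lowest median processed signal (198.4) and Hoshinoyume 2 the highest (314.5).

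Arrays of 1 cultivar correlated with each other at r of 0.986 to 0.995 across probes (median 0.993, 17 pairs of arrays), and arrays of different cultivars at 0.897 to 0.975 (median 0.932, 154 pairs). Across genes, which are not independent replicates, within-cultivar r had a median of 0.993 both for 11 pairs on 1 slide and for 6 pairs on different slides. Different cultivars on 1 slide correlated at a median of 0.953 (16 pairs). For the median probe, 91.3% of the variance lay between cultivars, against 33.3% given by chance with these group sizes. Akage and Hayayuki lay together at 1 end of the first principal component, with Sorachi, Yukara, Hoshinoyume and Kitaake at the other, and Norin No.15 stood apart on the second.

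**Figure D1:**
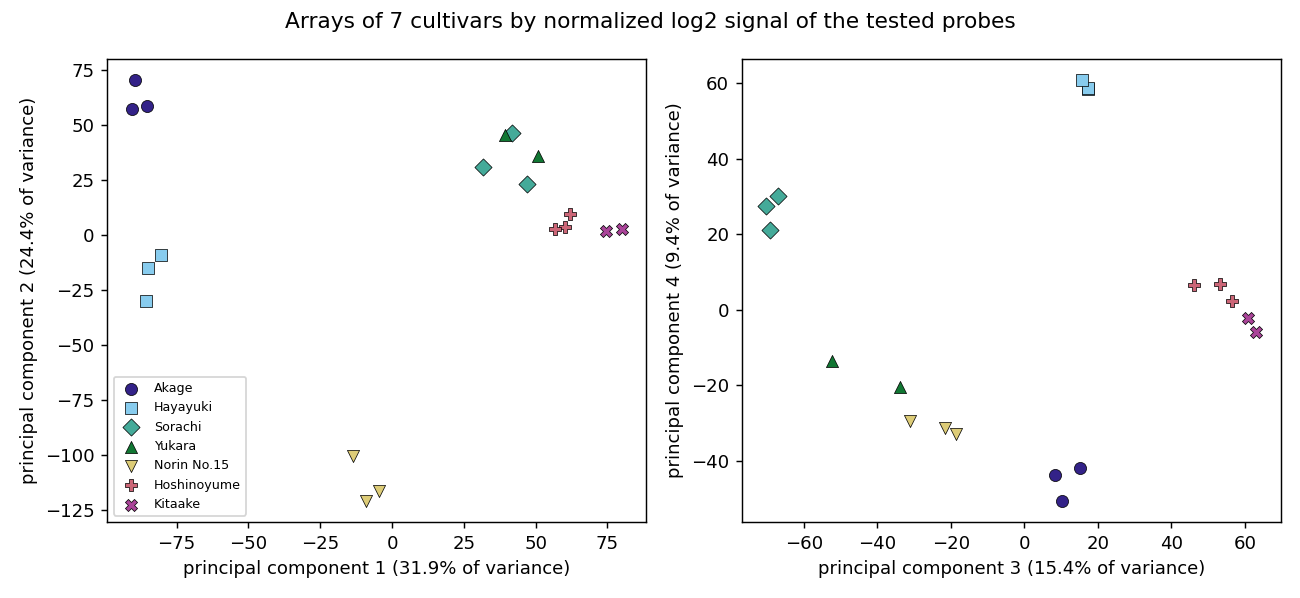
Each point is 1 of the 19 arrays, placed by principal components 1 and 2 (left) and 3 and 4 (right) of the normalized log2 signal of tested probes, in arbitrary units, with the colour and shape giving the cultivar. The components hold 31.9%, 24.4%, 15.4% and 9.4% of the variance, and arrays of 1 cultivar lie close together except where Sorachi and Yukara mix on the first 2 components.

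The first question was which transcripts differ among the cultivars at all. The largest ranges of cultivar means came from loci that were bright in some cultivars and not well above background in others. IN2-2 (Os04g0338100) was at least 1310-fold brighter in Norin No.15 than in Hayayuki. It was not well above background on any array of Akage or Hayayuki, and the other 5 cultivar means lay between 3.67 and 4.72 on the normalized log2 scale. The glycine-rich protein Os11g0209000 ranged at least 965-fold, with Hayayuki lowest, and the protein kinase Os02g0615800 at least 812-fold, with Hayayuki highest. The trypsin-like peptidase Os03g0109900 ranged at least 769-fold, with Hoshinoyume lowest. Defence-related genes were among them. The pathogenesis-related protein 1 gene Os07g0129300 ranged at least 173-fold, and its relative Os01g0382000 480-fold, with Akage, Hayayuki and Norin No.15 high. The Bowman-Birk proteinase inhibitor Os01g0127600 ranged at least 353-fold with Kitaake high. The terpene synthase-like Os08g0139700 ranged 429-fold with Sorachi alone low (-2.84 ± 0.61, SD, n = 3, against 4.86 to 5.9). The Clp protease subunit Os12g0230100 ranged 497-fold, with Akage and Hayayuki high. In limma's moderated F test, 26391 of 27946 probes (94.4%) differed among cultivars, and 14666 (52.5%) both differed and had a range of cultivar means of at least 1. By locus, 19629 of 20789 differed, 10961 with a range of at least 1 and 1915 with a range of at least 3. The median range was 1.08, against a median SD within cultivars of 0.135.

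Gene groups differed in how widely their members ranged. Cytochrome P450s, enzymes of many secondary pathways, had 131 of 165 tested loci (79.4%) past the test with a range of at least 1 (adjusted p = 3.8e-11, Fisher's exact test against all other loci). The share was 90.6% of jasmonate genes (29 of 32, adjusted p = 3.57e-05), 88.5% of diterpenoid phytoalexin enzymes (23 of 26, 0.000588) and 84.9% of WRKY factors (45 of 53, 1.46e-05). Next came 82.8% of flavonoid enzymes (24 of 29, 0.00282) and 80.9% of dividing-cell markers (38 of 47, 0.00033). It was 75.6% of receptor-like kinases (59 of 78, 0.000141), 74.4% of transposon-derived genes (58 of 78, 0.000426), and 72.3% of pathogenesis-related proteins (99 of 137, 3.27e-05). Shares of 71.7% of glutathione S-transferases (33 of 46, 0.0247), 71.2% of NB-ARC disease resistance genes (104 of 146, 3.44e-05) and 100% of the iron list (7 of 7, 0.0332) also passed. The other lists did not pass: 57 of 103 heat shock, 16 of 42 photosystem, 11 of 26 Calvin cycle, 145 of 263 ribosomal, and 21 of 36 nitrogen loci. Nor did 25 of 37 phosphate, 22 of 33 cold, 7 of 9 senescence, 3 of 3 root, 6 of 9 seed storage, 4 of 7 pollen and 15 of 25 heading-date loci. Without a minimum range, Fisher's exact test passed 0 of 24 lists (1 at an unadjusted p under 0.05, the ribosomal list with 257 of 263 loci, adjusted p = 0.345). There, limma called 94.4% of all loci. At a range of at least 3, chosen after seeing the data, 12 lists passed. So wide a range was seen in 62.5% of jasmonate genes (20 of 32), 57.7% of diterpenoid enzymes (15 of 26) and 30.7% of pathogenesis-related proteins (42 of 137). Ribosomal proteins had it in 1 of 263 (adjusted p = 2.82e-09, Fisher's exact test). This test takes loci as independent of each other, so its p-values are too small where members of a list vary together.

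Heading-date (flowering time) genes were followed by locus. The florigen gene Hd3a (Os06g0157700), whose product moves from leaf to shoot tip to start flowering, was highest in Hayayuki (-1.57 ± 0.31, SD, n = 3, normalized log2 signal), then Norin No.15 (-2.21 ± 0.13). It was not well above background on any Sorachi array, at least 18.5-fold lower than in Hayayuki. Ehd1 (Os10g0463400), an activator of Hd3a, ranged 10.1-fold from Hayayuki (-1.1 ± 0.23) to Sorachi (-4.43 ± 0.38), with Kitaake (-4.35 ± 0.11, n = 2) near the bottom. MADS14 (Os03g0752800), a flowering gene also expressed in leaves, ranged 98.5-fold from Norin No.15 (0.62 ± 0.17) to Sorachi (-6 ± 0.38, well above background on 1 of 3 arrays). Its other probes ranged by 1, 4.26 and 7.54 log2. Hd1 (Os06g0275000), a daylength-dependent regulator, was highest in Norin No.15 and not well above background in Akage, Hayayuki and Yukara (at least 5.39-fold). The casein kinase 2 alpha gene at the Hd6 locus (Os03g0762000) was 17.5-fold brighter in Akage than in the lowest cultivar. Akage, Hayayuki and Norin No.15 lay at 1.97 to 2.4 and the other cultivars at -1.73 to -1.56. The HAP3 gene Os08g0174500 (DTH8) ranged 5.4-fold, highest in Kitaake. Of the clock genes, PRR1 ranged by 2.56, PRR95 by 1.83, ELF3 by 1.39, PRR59 by 1.11, LHY by 0.97, GI and PRR37 by 0.96 each and PRR73 by 0.71 log2. Of the phytochromes, PhyA ranged by 1.33, PhyC by 1.14 and PhyB (Os03g0309200) by 0.28. The MADS-box genes MADS50, MADS15 and MADS51 ranged by 1.33, 1.31 and 0.77, Ehd3 and Ehd4 by 0.51 each and the casein kinase gene Hd16 by 0.36. All 25 loci passed limma's moderated F test, 25 of 25 also when adjusted over the list alone. Their adjusted p ran from 3.61e-12 (Os03g0762000) to 0.0369 (Os10g0419200, a zinc finger gene ranging by 0.59). The call of Os10g0419200 ended under normexp, without a filter, with an intensity trend in the prior and without any 1 of 11 arrays (adjusted p up to 0.322), and that of PhyB (Os03g0309200) without Kitaake 1 (0.0775).

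Over the 7 cultivar means, the level of Ehd1 went with that of Hd3a (Pearson's r = 0.83, exact permutation p = 0.00337, adjusted p = 0.00437; Spearman's rho = 0.96, exact p = 0.00278). This r was 0.96 without Sorachi and Kitaake, the cultivars farthest from the median Ehd1 level. Those 2 had similar Ehd1 levels but parted in Hd3a, which lay at -3.78 in Kitaake and was not well above background in Sorachi. The r values with Hd3a and with MADS14 (well above background on 1 of 3 Sorachi arrays) take the Sorachi signal as measured. Their size is therefore uncertain, while rho uses only its lowest rank. Hd3a went with MADS14 at r = 0.98 (exact permutation p = 0.000595, adjusted p = 0.00178; rho = 0.96, exact p = 0.00278; 0.98 without Sorachi and Hayayuki). The last of the 3 relations, between Ehd1 and MADS14, had r of 0.88 (exact permutation p = 0.00437, adjusted p = 0.00437) and rho of 0.93 (exact p = 0.00675). Its r was 0.95 without Sorachi and Kitaake. These genes were chosen for this test after their values were seen, and all tests are two-sided. The exact p-values take the 7 cultivars as independent of each other and are too small where cultivars are related. Across probes, cultivar means correlated at 0.977 for Hoshinoyume and Kitaake and at 0.975 for Sorachi and Yukara. No slide holds more than 2 cultivars, too few for a value within slides.

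**Figure D2:**
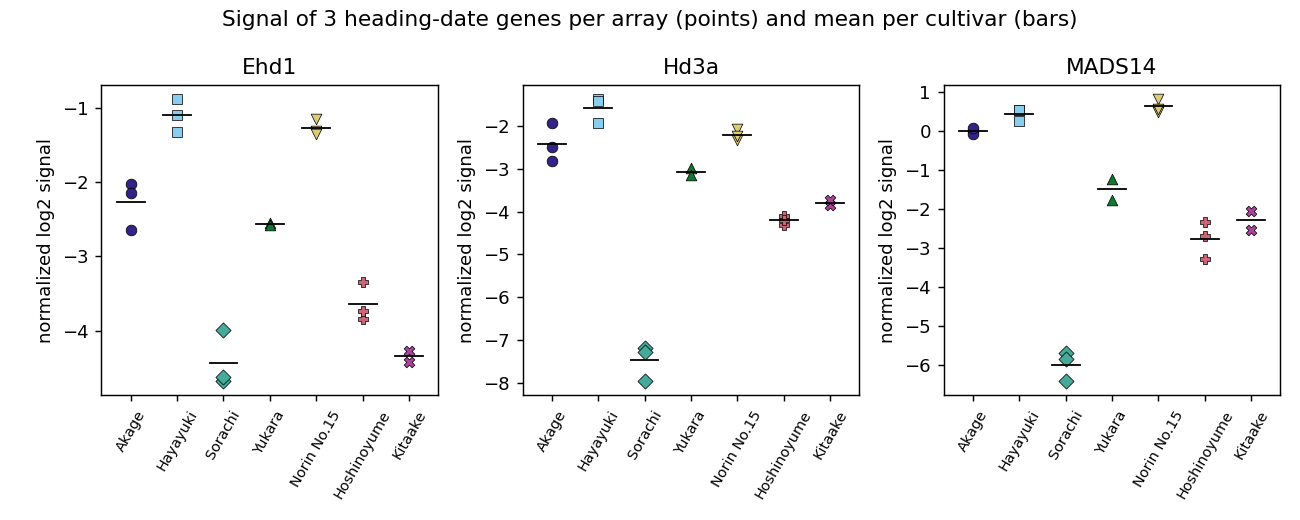
Normalized log2 signal (log2 of the processed signal minus the array's 75th percentile, vertical axis) of Ehd1, Hd3a and MADS14 in each cultivar (horizontal axis), with points for arrays and bars for cultivar means. Sorachi is lowest in all 3 panels, at -4.43, -7.48 and -6, and its Hd3a signal is not well above background.

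Each cultivar was then set against the mean of the other 6. A large change in 1 cultivar shifts the contrasts of the rest the other way, so a shift need not be particular to the cultivar named. In Akage, the flowering-related factor MADS56 (Os10g0536100) fell to a level not well above background on any of 3 arrays, at least 265-fold below the other cultivars (adjusted p = 2.21e-17). Genes of jasmonate, a wound and defence hormone, fell as a group: 23 of 32 tested loci fell, 2 rose and 7 did not pass (25 called when adjusted over the list alone), with a median of -1.33. Among them were Os06g0216300 (103-fold, -6.69 ± 0.31, well above background on 1 of 3 Akage arrays) and Os06g0216200 (96.4-fold, -6.59 ± 0.3), described as oxo-phytodienoic acid reductases. Whether these reductases act in jasmonate synthesis was not tested. The ZIM-domain genes Os10g0391400 (88.2-fold, -6.46 ± 0.19) and Os03g0180800 (55.5-fold), of a family that represses jasmonate responses, fell too. Photosystem genes rose in 34 of 42 loci and fell in 2 (36 when adjusted over the list alone, median 0.27), although the 22 kDa photosystem II protein gene Os04g0690800 was 4.7-fold lower. Ribosomal proteins fell in 162 of 263 loci and rose in 37 (201 alone, median -0.2), such as S10-1 (Os01g0962600, -1.16 ± 0.08), while L7a (Os01g0924800) rose by 1.12 ± 0.07. Dividing-cell markers fell in 23 of 47 and rose in 7 (30 alone, median -0.16), with the histone H2A gene Os03g0279200 at -1.84 ± 0.19 and the H3 gene Os06g0160100 at least 1.58-fold higher (adjusted p = 0.0821 under normexp). Of the lists marking other tissues, seed storage genes fell in 3 of 9 (median -0.48) and pollen genes rose in 4 of 7 and fell in 1 (0.36), with camera adjusted p of 0.184 and 0.414. Outside the lists, the disease resistance gene Os06g0267900 was at least 39.4-fold and the Piwi-domain gene Os02g0616300 at least 13.4-fold higher. The bHLH factor Os04g0301500 was 182-fold and the receptor kinase LRK14 (Os01g0114300) at least 27.5-fold lower. Another locus described as LRK14 (Os01g0115600) was higher, by 2.42 log2. Camera gave adjusted p of 2.37e-07 for the jasmonate list (adjusted p = 0.899 with an estimated correlation). The values were 6.02e-07, 0.00146 and 0.0142 for ribosomal, photosystem and dividing-cell lists (adjusted p = 0.917 with an estimated correlation for each). In all, 18486 probes were called, 9942 higher and 8544 lower, and 3817 by at least 1 log2. The photosystem call ended under quantile normalization (median 0.12, adjusted p = 0.158) and the dividing-cell call without Akage 1 (-0.07, 0.0661).

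In Hayayuki, histones and other dividing-cell markers rose in 35 of 47 loci and fell in 2 (38 when adjusted over the list alone, median 0.81), led by the histone H4 gene Os03g0119900 (4.81-fold, 2.26 ± 0.18) and the H2A gene Os12g0438000 (3.21-fold, 1.68 ± 0.1). Jasmonate genes fell in 21 of 32 and rose in 4 (26 alone, median -0.89). Within the list, allene oxide synthase (Os03g0225900, 12-fold, 3.59 ± 0.19) and the lipoxygenase Os08g0509100 (15.1-fold, 3.92 ± 0.32), of enzyme families that act early in synthesis, rose. The reductase Os06g0216300 (12.8-fold, -3.67 ± 0.31) and the ZIM gene Os09g0439200 (10.7-fold, -3.43 ± 0.3) fell. Among other-tissue lists, seed storage genes rose in 2 of 9 and fell in 1 (median -0.17) and root genes rose in 1 of 3 and fell in 1 (-0.18), with camera adjusted p of 0.684 and 0.842. The protein kinase Os02g0615800 was at least 723-fold higher, Os04g0369000 at least 33.7-fold, the bHLH factor Os04g0631600 at least 19.8-fold and the NBS-LRR gene Os11g0224900 at least 16.6-fold. The glycine-rich Os11g0209000 was at least 661-fold lower, and its neighbour Os11g0208900, a leucine-rich repeat gene, at least 58.3-fold. The Bowman-Birk inhibitor Os01g0127600 was at least 37.2-fold and the plasma membrane proton pump Os11g0660400 at least 21.5-fold lower. By camera, adjusted p was 1.29e-06 for dividing-cell markers and 4.98e-05 for jasmonate genes (adjusted p = 0.899 with an estimated correlation for both). In all, 16344 probes were called, 8896 higher and 7448 lower, and 3014 by at least 1 log2.

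In Sorachi, photosystem genes rose in 35 of 42 loci and fell in 2 (37 when adjusted over the list alone, median 0.33), led by the chlorophyll a-b binding protein Os01g0720500 (11.9-fold, 3.58 ± 0.3), its relative Os09g0439500 (6.5-fold, 2.7 ± 0.13) and the oxygen-evolving complex gene Os02g0578400 (at least 3.35-fold). Ribosomal proteins fell in 186 of 263 and rose in 17 (208 alone, median -0.23), but the 4 members that moved most rose. They were Os03g0751400 (L6, 3.1-fold), Os03g0828100 (L18, 2.67-fold) and Os01g0749200 (L13, 2.57-fold), all of the 50S type found in organelles, and an L17 gene (Os03g0815400, 2.4-fold). Pollen allergen and expansin-like genes, listed as markers of another tissue, rose in 5 of 7 (5 alone, median 0.53), with Os10g0555700 at least 3.79-fold higher and Os06g0725300 at 0.83 ± 0.1. The pollen-specific C13 gene Os04g0398700 differed by 0.53 ± 0.32 (adjusted p = 0.162). The BURP-domain gene Os10g0409400 was 45.1-fold higher (5.5 ± 0.52), the leucine-rich repeat gene Os01g0162300 23.6-fold and Viviparous-14 (Os07g0154100), named for an enzyme of abscisic acid synthesis, at least 9.96-fold. The terpene synthase-like Os08g0139700 was 316-fold lower (-8.3 ± 0.16). Further, Os02g0114700, the transferase Os08g0174100 and the receptor kinase Os07g0541400 were at least 21.2-fold, 17.8-fold and 15.2-fold lower. The camera test gave adjusted p of 6.52e-09 for photosystem genes, 2.37e-07 for ribosomal proteins and 0.0345 for the pollen list (adjusted p = 0.899, 0.917 and 0.899 with an estimated correlation). In all, 17304 probes were called, 7647 higher and 9657 lower, and 2612 by at least 1 log2. The pollen call ended without Sorachi 3 (median 0.22, adjusted p = 0.0708), under quantile normalization (0.6, 0.126), without a filter (0.04, 0.252) and with the all-array filter (0.22, 0.0684).

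In Yukara, ribosomal proteins fell in 208 of 263 loci and rose in 14 (230 when adjusted over the list alone, median -0.38), among them L10a-3 (Os08g0558000, 7.56-fold, -2.92 ± 0.73) and L6 (Os04g0473400, 2.42-fold). NB-ARC disease resistance genes fell in 47 of 146, rose in 16 and did not pass in 83 (61 alone, median -0.13, mean -0.51). Of these, Os11g0606400 was at least 48.5-fold, Os11g0605100 at least 23.5-fold and Os12g0204600 at least 13.2-fold lower. Photosystem genes rose in 32 of 42 and fell in 0 (33 alone, median 0.3), such as CP24 (Os04g0457000, 0.74 ± 0.11). The oxygen-evolving complex gene Os02g0578400 was at least 1.26-fold higher, and its call ended under normexp (0.12, adjusted p = 0.742). Dividing-cell markers fell in 22 of 47 and rose in 5 (27 alone, median -0.35), with the H4 gene Os03g0119900 at -1.73 ± 0.22 and the H2B gene Os05g0460500 at least 2.51-fold higher. The transferase Os08g0174100 was at least 40.6-fold higher and Os11g0596200 at least 14.8-fold. The beta-glucosidase aggregating factor Os12g0247700 was 149-fold (-7.22 ± 0.77), the oxygenase Os04g0182200 at least 51.8-fold and the cytochrome P450 Os07g0217600 at least 19.7-fold lower. Adjusted p by camera was 1.83e-20 for ribosomal, 9.92e-07 for photosystem, 0.0145 for NB-ARC and 0.0119 for dividing-cell loci (adjusted p = 0.899, 0.899, 0.899 and 0.917 with an estimated correlation). In all, 13429 probes were called in 2 arrays against the rest, 6626 higher and 6803 lower, and 2008 by at least 1 log2. The NB-ARC call ended under quantile normalization (median -0.08, adjusted p = 0.0639), without a filter (-0.12, 0.101) and with the all-array filter (-0.08, 0.387). The photosystem call ended under quantile normalization (0.1, 0.0504) and the dividing-cell call without Yukara 2 (-0.3, 0.109).

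In Norin No.15, 3 loci close together on chromosome 6 stood out. The cysteine proteinase Os06g0582600 was at least 544-fold, the receptor-like Os06g0581000 at least 318-fold and the protein kinase Os06g0581500 at least 174-fold higher. WRKY factors, many of them regulators of defence, rose as a group, with 36 of 53 higher and 7 lower (44 when adjusted over the list alone, median 1.07), such as WRKY70 (Os05g0474800, at least 5.81-fold). Likewise, 23 of 32 jasmonate genes were higher and 1 lower (24 alone, median 1.04), such as the lipoxygenase Os08g0509100 (21.9-fold, 4.46 ± 0.32), allene oxide synthase Os03g0225900 (15.6-fold, 3.96 ± 0.19) and the reductase Os06g0215600 (at least 10.1-fold). Glutathione S-transferases, detoxifying enzymes, rose in 27 of 46 and fell in 7 (36 alone, median 0.45), led by Os03g0785900 (9.27-fold, 3.21 ± 0.31). Dividing-cell markers fell in 41 of 47 and rose in 1 (42 alone, median -0.84), with the H4 gene Os02g0684500 4.59-fold lower. Photosystem genes fell in 37 of 42 and rose in 0 (37 alone, median -0.47), with Os01g0720500 7.01-fold lower. The iron list fell in 6 of 7 (7 alone, median -0.92), with the iron transporter IRT1 (Os03g0667500) at least 2.26-fold lower. For the photosystem and iron lists, this contrast cannot wholly tell the cultivar from its slide. Both lists were also lower in Norin No.15 than in the 1 Hoshinoyume array on the same slide. Ribosomal proteins rose in 158 of 263 and fell in 30 (189 alone, median 0.19), although L7a (Os01g0924800) was 6.28-fold lower (-2.65 ± 0.07). Of the lists marking other tissues, the pollen list fell in 6 of 7 and rose in 0 (median -0.45, camera adjusted p = 0.116). The beta-expansin Os10g0555900 was 56.4-fold (-5.82 ± 0.4) and the subtilase Os04g0127200 at least 12.5-fold lower. Under camera, adjusted p was 4.2e-08 for dividing-cell, 2.37e-07 for photosystem, 4.31e-07 for jasmonate, 1.29e-06 for WRKY, 0.00382 for glutathione S-transferase and 0.0352 for iron loci (adjusted p = 0.899 with an estimated correlation for each). It was 1.55e-06 for ribosomal proteins (adjusted p = 0.917 with an estimated correlation). In all, 18865 probes were called, 8287 higher and 10578 lower, and 4159 by at least 1 log2. The iron call ended under normexp (median -0.66, adjusted p = 0.0829), quantile normalization (-0.92, 0.0546), the all-array filter (-0.73, 0.118) and without Norin No.15 array 2 (-0.94, 0.0514).

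In Hoshinoyume, dividing-cell markers rose in 36 of 47 loci and fell in 1 (38 when adjusted over the list alone, median 0.73), such as the H2A gene Os03g0721900 (3.15-fold, 1.65 ± 0.11) and the H4 gene Os03g0119900 (2.84-fold, 1.51 ± 0.18). The marker Os11g0155900 was at least 1.63-fold higher, and its call ended under normexp (0.41, adjusted p = 0.126). WRKY factors fell in 26 of 53 and rose in 10 (37 alone, median -0.24), led by WRKY69 (Os08g0386200, 3.95-fold, -1.98 ± 0.24). Ribosomal proteins fell in 93 of 263, rose in 33 and did not pass in 137 (122 alone, median -0.06), with L7a (Os01g0924800) 5.97-fold lower (-2.58 ± 0.07). Of the lists marking other tissues, the root list rose in 1 of 3 (median 0.65, camera adjusted p = 0.483). The leucine-rich repeat gene Os02g0615400 was at least 269-fold, the F-box gene Os10g0137700 at least 27.9-fold and the kinase Os02g0615500 at least 24.5-fold higher. The aldehyde oxidase Os10g0138100, on chromosome 10 like the F-box gene, was at least 46.3-fold higher. The peptidase Os03g0109900 was at least 92.4-fold lower, and the kinase Os09g0355400 at least 7.31-fold lower, its other probe showing -2.31. Camera's adjusted p was 2.51e-10 for dividing-cell markers (adjusted p = 0.899 with an estimated correlation), 0.0317 for WRKY factors (adjusted p = 0.909 with an estimated correlation) and 0.0288 for ribosomal proteins (adjusted p = 0.936 with an estimated correlation). In all, 14117 probes were called, 7192 higher and 6925 lower, and 2013 by at least 1 log2. The ribosomal call ended in 6 of 31 settings (medians -0.07 to -0.03, adjusted p up to 0.287), without Hoshinoyume 3 (adjusted p = 0.0856) and Kitaake 2 (0.0568) among them. The WRKY call ended without Hoshinoyume 1 (-0.26, 0.0506) and with the all-array filter (-0.22, 0.0729).

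In Kitaake, ribosomal proteins rose in 224 of 263 loci and fell in 10 (237 when adjusted over the list alone, median 0.72), 60 of them by at least 1 log2. Examples were S10-1 (Os01g0962600, 4.22-fold, 2.08 ± 0.09), L30 (Os01g0812800, 3.92-fold, 1.97 ± 0.22) and S2 (Os07g0207400, 3.86-fold, 1.95 ± 0.09). Jasmonate genes rose in 19 of 32 and fell in 3 (25 alone, median 0.54), with the ZIM gene Os09g0439200 14-fold (3.8 ± 0.35) and the lipoxygenase Os12g0559200 7.66-fold higher. Allene oxide synthase (Os03g0225900) was 5.73-fold lower. WRKY factors fell in 25 of 53 and rose in 8 (33 alone, median -0.43), with WRKY24 (Os01g0826400) 5.22-fold lower and WRKY50 (Os11g0117600) 9.44-fold higher. Photosystem genes fell in 25 of 42 and rose in 1 (27 alone, median -0.22), with Os01g0720500 4.75-fold lower. Of the lists marking other tissues, seed storage genes rose in 4 of 9 and fell in 1 (median 0.74), root genes rose in 1 of 3 and fell in 1 (1.05), and pollen genes fell in 4 of 7 (-0.59). Their camera adjusted p was 0.596, 0.964 and 0.292. The cellulose synthase-like gene CslA3 (Os08g0434500) was 40.6-fold (5.34 ± 0.47), a transposase gene (Os04g0401400) at least 12.9-fold, the methyltransferase Os02g0719600 32.1-fold and the Bowman-Birk inhibitor Os01g0127600 at least 25.3-fold higher. The ARM-repeat gene Os12g0261300 was at least 18.4-fold and the BURP gene Os10g0409400 16.2-fold lower. The probes of the xyloglucan enzyme gene XET2 (Os06g0335900) disagreed (at least 8.97-fold lower, and -0.04 log2). In camera's test, adjusted p was 3.3e-31 for ribosomal and 0.017 for WRKY loci (adjusted p = 0.899 with an estimated correlation for both). It was 0.00193 for photosystem and 0.0204 for jasmonate loci (adjusted p = 0.917 with an estimated correlation for both). In all, 17081 probes were called, 9103 higher (53.3%) and 7978 lower, and 3554 by at least 1 log2. Under normexp, where the median of all probes lay at 0.2 in this contrast (0.04 otherwise), 67.1% of calls were higher. The jasmonate call ended under normexp (median 0.46, adjusted p = 0.102) and without Kitaake 1 (0.41, 0.101), and the photosystem call under quantile normalization (-0.07, 0.169).

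**Figure D3:**
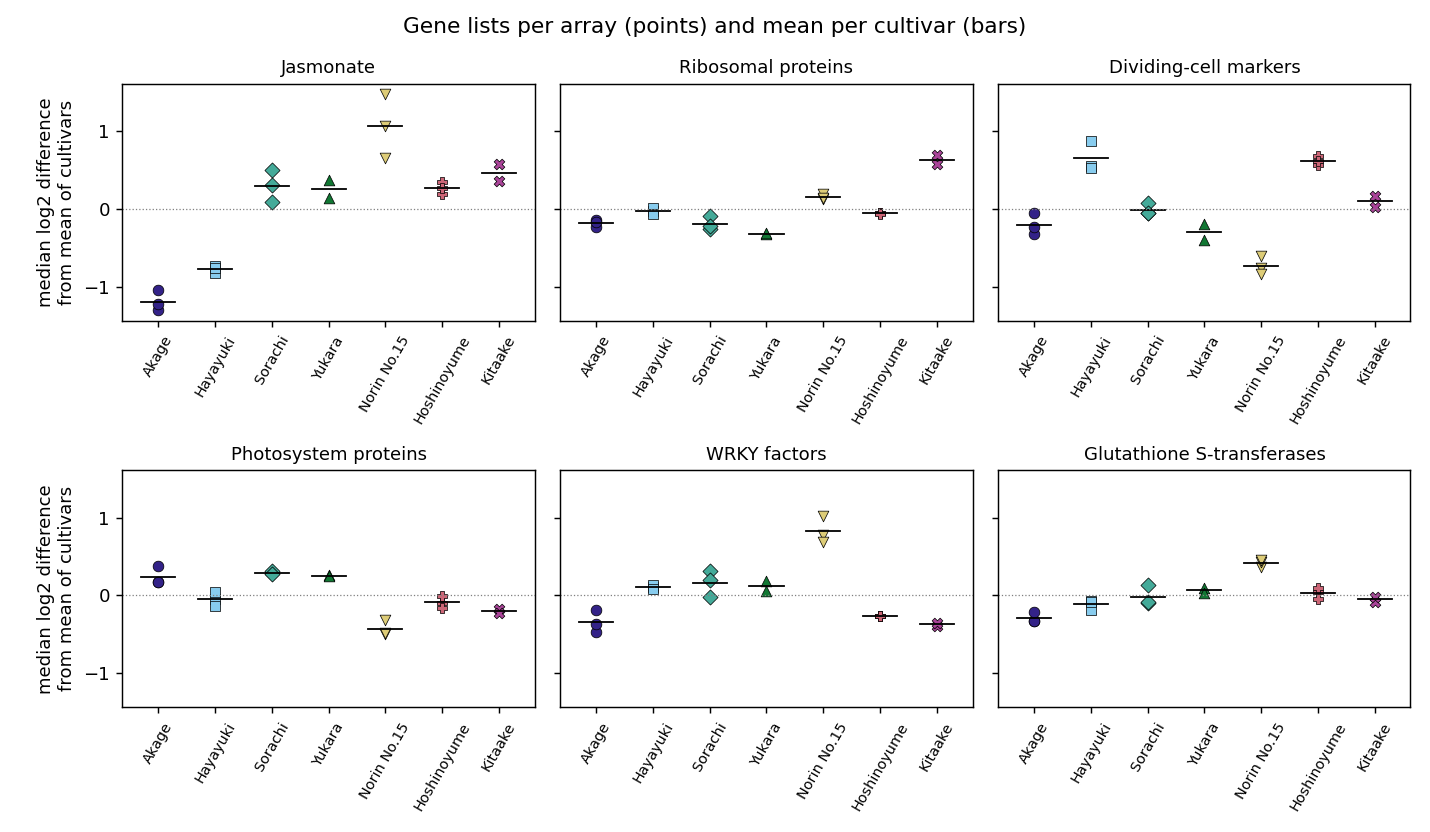
Median over a list's tested loci of the log2 difference from the mean of the 7 cultivar means (vertical axis) on each array (points), by cultivar (horizontal axis), with bars for cultivar means. Jasmonate genes lie at -1.19 in Akage, -0.78 in Hayayuki and 1.06 in Norin No.15, ribosomal proteins at 0.63 in Kitaake, and dividing-cell markers at 0.65 in Hayayuki, 0.62 in Hoshinoyume and -0.74 in Norin No.15.

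Of the 192 list tests, camera called 29 at the preset correlation and 0 with an estimated correlation (10 at an unadjusted p under 0.05), and fry passed 102. No list of receptor-like kinases, pathogenesis-related proteins, diterpenoid enzymes, heat shock proteins, Calvin cycle enzymes, flavonoid enzymes, cytochrome P450s, nitrogen, phosphate, transposon, cold, senescence, root, seed storage or heading-date genes was called in any contrast at the preset correlation. With slide as a random block, the same 29 list calls were made. The correlation of this block was below 0 (-0.079), and it made the test over all cultivars no stricter. With it 19975 of 20789 loci passed, against 19629 without it. Nor can it separate slides 1 to 3 from slides 4 and 5, which share no cultivar, so it is no check on slide. Iron-list means of array medians were 0.63 (Akage), 0.22 (Hayayuki), 0.54 (Sorachi) and 0.09 (Yukara) on slides 1 to 3. On slides 4 and 5 they were -0.69 (Norin No.15), -0.15 (Hoshinoyume) and -0.32 (Kitaake). Photosystem means were 0.24, -0.05, 0.29 and 0.25, against -0.42, -0.09 and -0.2, in the same order. For both lists, contrasts across these slide sets cannot tell slide from cultivar. Brightness-matched lists were not drawn for them. Within slide 1, the jasmonate list differed by a median of -0.46 between Akage and Hayayuki (-0.57 over all arrays), dividing-cell markers by -0.81 (-0.9), photosystem genes by 0.29 (0.32) and ribosomal proteins by -0.14 (-0.15). Within slide 2, Hayayuki minus Sorachi, the jasmonate list differed by -1.07 (-1.01), dividing-cell markers by 0.72 (0.72), photosystem genes by -0.35 (-0.33), ribosomal proteins by 0.15 (0.15) and the pollen list by -0.38 (-0.47). On slide 3, Sorachi minus Yukara, the values were 0.09 (0.13) for ribosomal, 0.03 (0.05) for photosystem, -0.1 (-0.04) for NB-ARC and 0.47 (0.4) for pollen loci. Within slide 4, Norin No.15 minus Hoshinoyume, they were 0.79 (0.9) for jasmonate, 0.74 (0.79) for WRKY, -1.37 (-1.26) for dividing-cell, 0.19 (0.2) for ribosomal, -0.3 (-0.27) for photosystem, 0.16 (0.18) for glutathione S-transferase and -0.76 (-0.62) for iron loci.

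Hoshinoyume and Kitaake, both of group V, were the most alike pair by correlation of cultivar means (r = 0.977 across probes). Kitaake had more ribosomal protein transcript, with 224 of 263 loci lower in Hoshinoyume and 1 higher (233 when adjusted over the list alone, median -0.73), led by L7a (Os01g0924800, 7.98-fold, -3 ± 0.1) and L32A (Os09g0502000, 3.41-fold, -1.77 ± 0.08). Hoshinoyume had more of the dividing-cell markers, with 25 of 47 higher and 2 lower (28 alone, median 0.45), such as the H4 gene Os09g0553100 (2.74-fold, 1.46 ± 0.16) and the H2B gene Os08g0490900 (2.76-fold, 1.46 ± 0.22). The pollen list rose in 2 of 7 (median 0.32, camera adjusted p = 0.119) and the root list in 1 of 3 (-0.07, 0.587). The seed storage list, not called either, had a median of -0.41. Cyclin A2 (Os12g0502300, at least 1.7-fold higher) turned to -0.24 under normexp (adjusted p = 0.566). The leucine-rich repeat gene Os02g0615400 was at least 311-fold, the aldehyde oxidase Os10g0138100 at least 54.4-fold and the ankyrin gene Os09g0343200 at least 35.5-fold higher in Hoshinoyume. The peptidase Os03g0109900 was at least 431-fold, a ribosomal RNA methylase gene (Os05g0511700) at least 95.4-fold, the transposase Os04g0401400 at least 50.1-fold and the NBS-LRR gene Os08g0205100 at least 14.4-fold lower. Camera gave adjusted p of 3.23e-54 and 1.16e-05 for the ribosomal and dividing-cell lists (adjusted p = 0.899 with an estimated correlation for both). With slide as a fixed block it gave 6.06e-51 (median -0.74) and 0.000186 (0.42), with adjusted p = 0.59 and 0.812 with an estimated correlation, and the medians within slide 5 were -0.74 and 0.42. In all, 9082 probes were called, 4317 higher in Hoshinoyume (47.5%) and 4765 lower, 1374 by at least 1 log2 (658 higher, 716 lower). There were 7684 calls with slide as a fixed block and 7895 within slide 5. Under normexp, where the median of all probes lay at -0.17 (-0.01 otherwise), 30.4% of calls were higher. The count was 6038 without Kitaake 1 and 5596 without Kitaake 2.

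Sorachi and Yukara, of groups IIIa and IIIb, had the fewest calls of any pair without a size limit, and the second fewest, after Hoshinoyume and Kitaake, at 1 log2 or more. Among the loci higher in Sorachi were 4 disease resistance genes on chromosome 11, Os11g0606400 (at least 67.7-fold), Os11g0684100 (at least 60-fold), Os11g0639600 (at least 47.7-fold) and Os11g0605100 (at least 26.7-fold). The isopiperitenone reductase gene Os02g0640800, of a monoterpene enzyme family, was 62.2-fold higher (5.96 ± 0.35). Yukara had at least 283-fold more of the transferase Os08g0174100 and at least 91.8-fold more of the ribosomal RNA methylase gene Os05g0511700. It had 323-fold more of the terpene synthase-like Os08g0139700 (-8.34 ± 0.24, Sorachi minus Yukara) and 66-fold more of the proteasome subunit gene Os11g0615700 (-6.05 ± 0.08). In limma, 7107 probes were called, 3249 higher and 3858 lower in Sorachi, and 1400 by at least 1 log2, 862 higher and 538 lower. Lists were not tested with camera on all arrays for this pair. With slide as a fixed block, the ribosomal list differed by a median of 0.09 (camera adjusted p = 0.00142, adjusted p = 0.821 with an estimated correlation). The count was 2001 with slide as a fixed block, 106 within slide 3 (1 array against 2), 4248 under normexp and 3628 without Yukara 2.

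Over the 21 pairs, the median was 16570 called probes. Akage and Kitaake were the least alike, with the lowest correlation of cultivar means (0.913) and the most calls of at least 1 log2 (6913), followed by Akage and Norin No.15 (6209). Akage and Hayayuki differed by at least 1 log2 in 3031 probes and Yukara and Hoshinoyume in 2757. Within slide 2, with 2 arrays of each cultivar, 10543 probes were called between Hayayuki and Sorachi. Slides 1 (Akage and Hayayuki) and 4 (Norin No.15 and Hoshinoyume) hold 3 arrays against 1, and the single array gives no spread of its own. Differences there correlated with those over all arrays, which include them, at r of 0.969 and 0.985 across probes.

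Loci set apart in 1 cultivar lay in groups along the chromosomes in 6 of the 7 cultivars. A locus was taken as set apart if all arrays of the cultivar lay outside the range of all others, with a called difference of at least 2 log2, a definition chosen after seeing the data. In Norin No.15, 13 of the 15 tested loci from Os06g0579000 to Os06g0583500 on chromosome 6 were set apart and all 13 were higher, by at least 2210-fold at Os06g0580100. In Akage, 10 of 19 loci from Os01g0113300 to Os01g0115900 on chromosome 1 were set apart, 8 of them lower. Most of these 10 are described as protein kinases, receptor-like kinases or LRK genes, a theme that was not tested. Groups in other cultivars held 6 of 8 loci in Hayayuki (chromosome 11, from the NBS-LRR gene Os11g0224900, all higher), 7 of 8 in Hoshinoyume (chromosome 9, from Os09g0354300) and 6 of 9 in Yukara (chromosome 10, with the RIR1 genes, all lower). In Sorachi, 5 of 6 loci on chromosome 7, among them receptor kinases, formed such a group. Each stretch was the densest 20 tested loci in a row, cut to its first and last set-apart locus, so these shares are high by construction. The highest count in 10000 permutations was 7 in Norin No.15, 7 in Akage and 5 in Hoshinoyume (permutation p = 1e-04 each). It equalled the observed count in Hayayuki (6), Yukara (6) and Sorachi (5), with permutation p of 0.0003, 0.0002 and 0.0004. In Kitaake, no 20 tested loci in a row held more than 3 (permutation p = 0.994). In all, 462 loci were set apart in Norin No.15, 424 in Akage, 255 in Kitaake, 219 in Hayayuki, 198 in Yukara, 128 in Sorachi and 105 in Hoshinoyume. Without a call or a size limit, all arrays lay outside the range of all others at 4247 of 20789 loci in Kitaake, 3553 in Akage, 3296 in Norin No.15, 2372 in Sorachi, 1569 in Hayayuki, 1369 in Yukara and 905 in Hoshinoyume. If all 19 arrays were interchangeable, chance would give 0.206% of loci for 3 arrays and 1.17% for 2. Arrays of 1 cultivar resemble each other, so these shares are too low a baseline, and the counts by themselves show no excess. Both loci of a neighbouring pair were set apart in 49 pairs in Norin No.15 (10.2 by chance), 36 in Akage (8.6), 21 in Yukara (1.9), 17 in Hayayuki (2.3), 11 in Hoshinoyume (0.5) and 10 in Sorachi (0.8). Each had permutation p = 1e-05, the smallest that the permutations can give. Kitaake had 10 such pairs (3.1 by chance, permutation p = 0.00116). For all 19629 differing loci, the planned test, 18541 neighbouring pairs were both called against 18523.0 by permutation (p = 0.0135, one-sided). With a range of at least 1 there were 6114 against 5775.7 (permutation p = 1e-05). The first of these calls ended under quantile normalization (permutation p = 0.0595), a prior with an intensity trend (0.184), the replicate block (0.0899), array weights (0.188), slide as a fixed block (0.157) and without any 1 of 6 arrays (up to 0.279).

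**Figure D4:**
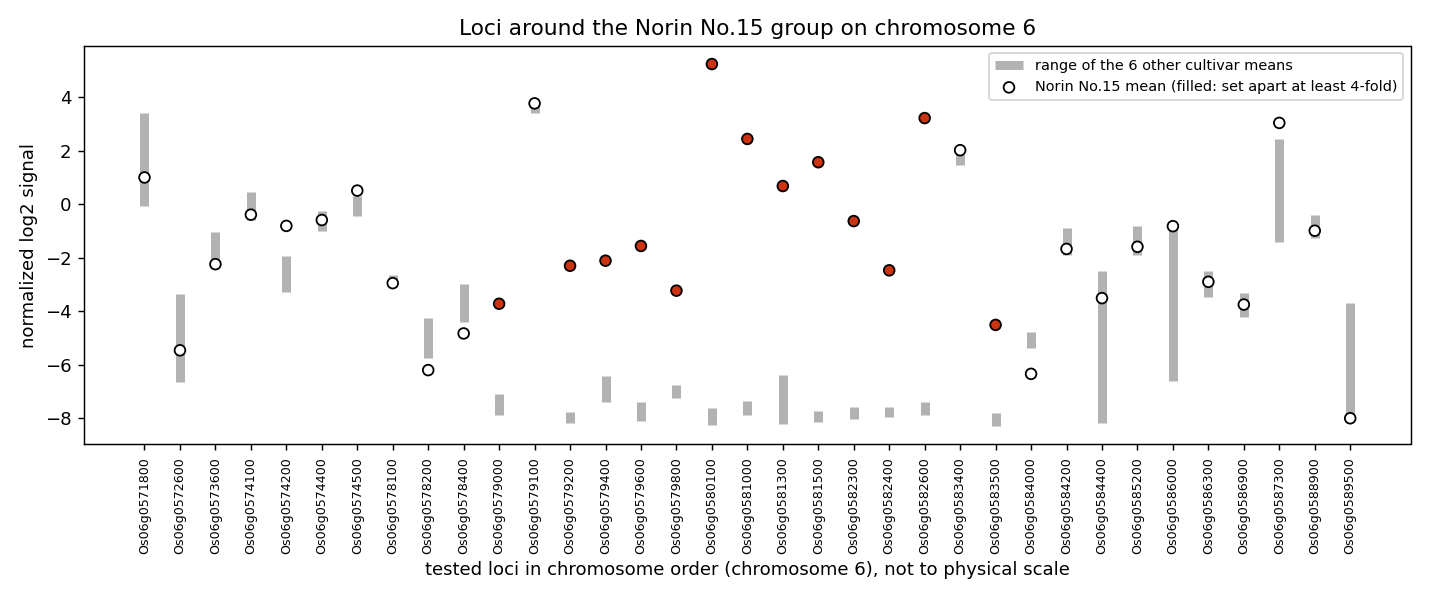
Normalized log2 signal (vertical axis) of tested loci in their order on chromosome 6 (horizontal axis, not to physical scale), with circles for the Norin No.15 mean of 3 arrays (filled where set apart at least 4-fold) and grey bars for the range of the other 6 cultivar means. The 13 filled circles run from Os06g0579000 to Os06g0583500, with the highest, Os06g0580100, at 5.24 against -8.24 to -7.61 in the other cultivars, where it is not well above background.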

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

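The tests of slide, clock hours, tandem copies, dividing cells and other splits of the arrays were chosen only after the result was seen, while those of a sequence variant under 1 probe and of scaling by brightness were set before it was seen. The arrays carry spike-in controls that no comparison used. Their signal stood out because 7 of the spike-in transcripts were well above background on all 19 arrays. Their mean level against the array's 75th percentile was 2.23 log2 over the 11 arrays of slides 1 to 3 (2.06 to 2.44) and 1.93 over the 8 arrays of slides 4 and 5 (1.76 to 2.11), sets that share no cultivar.

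In each cultivar, loci set apart at least 4-fold lay next to each other more often than chance gives. A sequence variant under 1 probe is argued against where another tested probe exists. Of 334 such cases, 308 (92.2%) showed at least 0.5 of the difference in the other probes, and 3 went the opposite way. The rest of the 1791 cases had no other tested probe and were not covered. A locus counts as a case in each cultivar where it was set apart. Tandem copies sharing 1 description are argued against too, since the excess of neighbours held in 7 cultivars with such neighbours taken as 1, though in Kitaake at permutation p = 0.0176. Only identical descriptions were merged, so tandem families described in different words, such as kinases in the Akage group, were not tested and remain possible. Of the 1791 cases, 868 were lower and 350 of these were not well above background. Genes deleted in a cultivar, stretches with several variants, or regulation shared by neighbours may therefore each account for part. None of these was tested without genome sequence. The groups of neighbours are therefore a hypothesis of stretches that differ between cultivars, found and tested on the same data.

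The jasmonate list was lower in Akage and Hayayuki than in the other 5 cultivars, though its camera calls in both ended when the correlation was estimated from the data. Slide is argued against for Hayayuki, whose list differed from that of Sorachi by a median of -1.07 on the same slide (SD 0.05 between Hayayuki arrays), and the 3 Hayayuki arrays lay at -0.83 to -0.74 over slides 1 and 2. Harvest at hours apart on the clock cannot be told apart from a cultivar difference, because the labels give no hour. The 8 core clock loci had a median range of 1.04, at percentile 47.5 of all tested loci, against 3.29 for jasmonate loci, but PRR1 and PRR95 ranged more, and the bound for this test was set after those values were known. Wounding before harvest and inherited differences between the cultivars, which the design names, may also contribute and were not tested.

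The ribosomal protein list was higher in Kitaake, where lists marking other tissues had medians of 0.74 (seed storage), 1.05 (root) and -0.59 (pollen). Its camera call in Kitaake ended when the correlation was estimated from the data. Scaling that depends on brightness is argued against, since 95% of 10000 brightness-matched lists had medians from -0.08 to 0.05, against 0.72 for the list. Slide is argued against by the difference of -0.74 between Hoshinoyume and Kitaake within slide 5 (SD 0.01 between Hoshinoyume arrays). More dividing cells than in Hoshinoyume are argued against, as the markers were higher in Hoshinoyume by a median of 0.45 (adjusted p = 0.899 with an estimated correlation), but against all 6 other cultivars the markers rose in 21 of 47 loci and fell in 8 in Kitaake (median 0.1, camera adjusted p = 0.462), so more dividing cells cannot be told apart there. A younger leaf, a different hour of harvest or an inherited difference may remain behind it and were not tested.

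Other splits of the 19 arrays into groups of the same sizes were fitted with missing values filled, which changes counts slightly. For every result tested so, only the real grouping, 1 of 100 splits, gave a count as large. That share is the smallest that 100 splits can give, and the 11 results share the same splits. Other splits mix cultivars, which moves cultivar differences into the spread, so their low counts were largely fixed in advance. The comparison shows that arrays of 1 cultivar resemble each other and is no separate check of each result. The real count and the highest of the others were 26401 and 2004 for the test over all cultivars, 18505 and 5712 for Akage, 16409 and 32 for Hayayuki, and 17321 and 450 for Sorachi. They were 13452 and 2106 for Yukara, 18880 and 1103 for Norin No.15, 14150 and 3255 for Hoshinoyume, and 17096 and 152 for Kitaake. For the median pair they were 16612 and 220, for Hoshinoyume against Kitaake 9120 and 58, and for Sorachi against Yukara 7131 and 75. For pairs of cultivars with 3 arrays each, the 10 splits of the 6 arrays are too few for a share under 0.05. Their real counts and highest others were 13472 and 2 (Akage and Hayayuki), 16861 and 1 (Akage and Sorachi), 19185 and 0 (Akage and Norin No.15), 17461 and 0 (Akage and Hoshinoyume) and 17329 and 0 (Hayayuki and Sorachi). The rest were 15733 and 1 (Hayayuki and Norin No.15), 16189 and 0 (Hayayuki and Hoshinoyume), 18085 and 0 (Sorachi and Norin No.15), 15577 and 1 (Sorachi and Hoshinoyume) and 16148 and 0 (Norin No.15 and Hoshinoyume).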

How the results depend on the processing

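The fits within slide 5 and within slide 3 and the lists at a range of at least 3 were chosen only after the result was seen. Signal over background limits the values of dim probes, and 2 or 3 arrays per cultivar limit precision. The count over all cultivars, the counts for each cultivar and the median over pairs stayed within 1.5 times the reported count in every alternative run, except when a size of at least 1 log2 was required. Then they were 14666 over all cultivars, 3817 for Akage, 3014 for Hayayuki, 2612 for Sorachi, 2008 for Yukara, 4159 for Norin No.15, 2013 for Hoshinoyume, 3554 for Kitaake, 1374 for Hoshinoyume against Kitaake, 1400 for Sorachi against Yukara and 4542 for the median pair, as the added condition removes smaller differences. Leaving out 1 array gave 5596 to 9367 calls for Hoshinoyume against Kitaake, where only the fits without Kitaake 1 (6038) and Kitaake 2 (5596) left a single Kitaake array, assumed to vary like the other cultivars. For Sorachi against Yukara it gave 3628 to 7471, lowest without Yukara 2. That pair also had 4248 calls under normexp, 2001 with slide as a fixed block, 2747 with only the arrays of these 2 cultivars and 106 within slide 3, where fewer arrays enter the last pair of fits and the other causes were not tested. Agreement of replicates ranged from 0.9913 to 0.9955. Among lists of differing loci, the count of 0 became 2 under normexp, 3 under quantile normalization, 12 without a filter, 1 with an intensity trend, 2 with slide as a fixed block, 12 with a range of at least 1 and 12 with a range of at least 3, and 0 to 1 without 1 array (1 without Akage 1, Norin No.15 array 1 or 2, Hoshinoyume 1 or 3, or Kitaake 2). The cause was not tested. Of the 29 list calls, 0 were left with an estimated correlation and fry gave 102. With slide as a fixed block, 3 list calls were made in the 2 described pairs, and 0 with an estimated correlation, an alternative chosen after seeing the data. Of the 29 calls, 18 held in all 31 settings of camera at the preset correlation, 11 ended in at least 1, 7 of them without 1 array, and 0 changed direction. Among the 31 settings, the deposited table of the series repeats the main values and so keeps every call. Neighbouring pairs lost their excess past the threshold under quantile normalization (18285), an intensity trend (18600), array weights (19429) and slide as a fixed block (11808). They ranged from 17818 to 18638 without 1 array, with permutation p over 0.05 without Hayayuki 1 (0.14), Yukara 1 (0.0709), Yukara 2 (0.176), Norin No.15 array 1 (0.106) or 3 (0.279) and Hoshinoyume 2 (0.0592), and the cause was not tested. Replicate numbers do not pair the samples, since 52 same-numbered pairs of arrays had deviations correlating at -0.23 to 0.27 (8 over 0.1) and 7 of 19 arrays correlated best with their own number. With the replicate block, counts were 26203 over all cultivars, 8433 for Hoshinoyume against Kitaake and 6446 for Sorachi against Yukara. The same 29 list calls were made, and neighbouring pairs were 18225 (permutation p = 0.0899). Most named loci were chosen for large differences past the test, and most settings leave out only 1 array. Their values under alternatives are therefore not independent checks and were likely to hold. Of 8316 such values, 8284 kept their call and direction, 30 fell short of the threshold, 1 passed it newly and 1 reversed, cyclin A2 (Os12g0502300) in Hoshinoyume against Kitaake under normexp (-0.24). The cause was not tested. Array weights were lowest for Akage 1 (0.39) and Hayayuki 2 (0.42).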

Other observations

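The tests and counts given here were chosen only after the result was seen. Some loci divided the cultivars into a high and a low set with a gap of at least 8-fold between them. There were 380 such loci, and they followed 40 of the 63 ways to divide 7 cultivars. The commonest parted Akage and Hayayuki from the other 5 cultivars (61 loci, 47 lower and 14 higher in these 2), then Akage alone (47 loci, 40 lower), Hayayuki alone (31, 13 lower), Norin No.15 alone (31, 12 lower) and Yukara alone (28, 23 lower). Akage, Hayayuki and Norin No.15 shared 19 loci, 16 of them higher, and Yukara, Hoshinoyume and Kitaake shared 12, all higher. Hoshinoyume and Kitaake, of the same group, were parted together from the rest at 8 loci.

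Probes for microRNA precursors carry no locus and entered no gene list. Of 428 on the array, 92 were tested, and 78 of these passed limma's moderated F test, 46 with a range of cultivar means of at least 1. The 3' sequence of osa-miR419 was at least 5.71-fold brighter in Kitaake than in Yukara (adjusted p = 0.000199), and it was not well above background on any array of Akage, Hayayuki, Sorachi or Yukara. The 5' sequence of the same precursor ranged by 2.39 in another order, from 3.3 in Akage to 0.91 in Hoshinoyume (adjusted p = 3.3e-07). A 5' sequence of osa-miR160f was at least 3.08-fold brighter in Akage than in Norin No.15, where it was not well above background.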
